A study of Macaca mulatta with 6 samples.

How the data were processed

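Gene expression was measured in the left adrenal gland of 6 ovariectomized female rhesus macaques. Per the labels, 1 animal was collected at each of 3 AM, 7 AM, 11 AM, 3 PM, 7 PM and 11 PM after housing under 12 h of light and 12 h of dark, with food withheld before collection. The hour of lights-on is not given in the sources used here. Per the labels' protocols, total RNA was purified on silica columns, copied from an oligo-dT primer carrying a T7 promoter, transcribed in vitro with biotinylated nucleotides and hybridised to an Affymetrix human expression array, 1 array per animal.

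The deposited values are one intensity per probe set and array on a linear scale, as read from the values themselves: they run from 0.1 to 40394. The trimmed mean of each array, with 2% cut from each end, lies between 325.04 and 325.09, so the authors' values had already been scaled to a common level. The software and the summary method that made these values are not given in the sources used here. Because the probes were designed on human sequence, a macaque transcript that differs from the human one can give a lower signal, and levels were compared only within a probe set. The table holds 22283 probe sets, of which 68 are controls. In the platform annotation, 19065 probe sets name 1 gene, 1043 name several and 2107 name none; probe sets naming several genes were not used to name a gene.

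Values were converted to log2(value + 1). Each gene was represented by the probe set with the highest mean among those that name that gene alone. Genes were kept where this mean was at or above the median of all probe sets that are not controls, a log2 value of 7.30, which left 7164 of 11963 genes. Fold changes are on the log2(value + 1) scale.

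The main test fitted a cosine with a period of 24 h to each gene over the 6 arrays with limma 3.58.1 in R 4.3.3 and tested the cosine and sine terms together with the moderated F test, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit leaves 3 residual degrees of freedom, and the error is the spread of single animals around the curve, since no clock time has a second animal. Peak-to-trough ratios come from the fitted curve and their errors are standard errors of the fit. A looser count took genes with an unadjusted p under 0.05 and a fitted peak at least 1.5 times the trough. As an exact test, R2 of the curve was compared over the 60 distinct circular orders of the 6 arrays, in which the smallest p is 0.0167. A contrast of 7 AM, 11 AM and 3 PM against 7 PM, 11 PM and 3 AM was fitted with limma, 3 arrays against 3. These arrays can be parted into 3 and 3 in 10 ways, so an exact test cannot go below 0.1.

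Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. They covered the core clock and its outputs, clock kinases and adaptors, steroidogenesis, cholesterol synthesis and uptake, chromaffin cells, immediate early genes, glucocorticoid-responsive genes, heat shock genes, Wnt and zona glomerulosa genes, oxidative phosphorylation, the proteasome, ribosomal proteins and the cell cycle. Marker lists covered endothelial cells, macrophages, lymphocytes, red blood cells, adipocytes, smooth muscle cells, fibroblasts and capsule, Schwann and glial cells and kidney. The mean of the members' standardized profiles was tested over the 60 orders, two-sided in the sense that any peak time counts, with adjustment over lists. A list's median F was also set against 10000 random lists matched on mean expression. For the daytime contrast, camera in limma was run on the lists with its preset correlation and with an estimated one, a test added after the data had been seen.

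The named genes are the 12 with the smallest p of the cosine fit, every measured clock gene, the 2 members with the smallest p from each other list, and the 3 genes with the smallest p in each direction of the daytime contrast among those differing at least 1.5-fold. Other genes that are named were chosen after their values were seen.

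The fits were tested on simulated data with the 7164 genes. Of genes given a 4-fold cosine, 94.0% passed an unadjusted p of 0.05 and 28.4% passed after adjustment; for 8-fold these were 98.5% and 65.2%, and for 2-fold 68.7% and 1.49%. Of unchanged genes 5.33% passed the unadjusted threshold. In the daytime contrast, 32.8% of 2-fold and 80.6% of 4-fold changes passed after adjustment. Each fold was given to 66 or 67 genes. The simulated noise was independent between genes and took its size from the residuals of the cosine fit, also for the daytime contrast. Variation within each part of the day and shared variation between genes were absent, so these shares are not the power in the real arrays. The number of arrays limits the precision throughout.

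Alternatives were no filter on level, a stricter filter on level, quantile normalization, centring on the median, every probe set on its own, limma with a trend and robust prior, age as a covariate, a pseudocount of 16, a floor at the 20th percentile, other minimum folds, the ordinary F test, other splits of the day, the first principal component of a list, and each array left out in turn. The fits without both the 3 AM and 3 PM arrays, the ordinary F test of the clock genes, and the chromaffin, adipocyte, immediate early and lymphocyte calls over the list alone without each array were added after the data had been seen. Plots were drawn with matplotlib 3.10.9.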

Results

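The series asked how gene expression in a primate adrenal gland varies over the day. The adrenal holds a cortex, which makes steroid hormones, and a medulla of chromaffin cells, which make adrenaline and noradrenaline. Adrenal RNA from 6 macaques was hybridised to 6 arrays, 1 animal at each of 6 clock times spaced 4 h apart, so no clock time was replicated.

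The arrays resembled each other, with correlations across probe sets between 0.916 and 0.928, where probe sets are not independent replicates. Median intensity ran from 154 at 7 AM to 173.1 at 3 PM. The hybridisation controls, transcripts added in fixed amounts, had a geometric mean of 415 at 3 AM and 539 at 3 PM, against 791 to 902 on the other 4 arrays. The 3'/5' signal ratio of the GAPDH control, a measure of RNA integrity, lay between 0.721 and 1.16, and that of ACTB between 0.610 and 0.819. The animals' ages followed the clock: 12 years at 3 AM and 7 AM, 10 years and 37 days at 11 AM, 8 years and 106 days at 3 PM, 7 years and 82 days at 7 PM, and 8 years and 70 days at 11 PM. A 24-h cosine fitted to age peaked at 6.23 h with an R2 of 0.947 (exact p = 0.0667 over the 60 orders).

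The clearest 24-h pattern lay in genes of the molecular clock, the transcriptional feedback loop that keeps circadian time, although the animals' ages followed a similar course. PER2, a repressor of that loop, had a fitted peak at 8.47 h and a peak 7.09 times its trough (log2 2.83 ± 0.27, SE), with intensities from 1248 at 7 AM down to 196 at 7 PM. BMAL1 and NPAS2, activators of the loop, ran opposite to it, with peaks at 17.4 h and near 20 h and peak-to-trough ratios of 2.89 and 3.49. The repressors BHLHE40 and BHLHE41, the nuclear receptor NR1D2 and the output factors HLF and TEF peaked between 5.55 h and 6.83 h, while NFIL3, a repressor that competes with HLF and TEF for binding sites, peaked near 16 h.

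Of 19 clock genes listed, 16 were on single-gene probe sets and 13 were tested. Of these, 9 passed by limma's moderated F test when adjusted over the list alone, and 0 when adjusted over all genes tested. By the ordinary F test 1 passed over the list alone, PER2, and 5 of the 13 passed the unadjusted threshold, against 9 with moderation, the other 4 being BMAL1, BHLHE40, NPAS2 and BHLHE41. The adjusted p over the list alone was 0.000397 for PER2, 0.00988 for BMAL1, NPAS2 and BHLHE41, 0.0207 for HLF and BHLHE40, 0.0215 for NR1D2, 0.0429 for NFIL3 and 0.0453 for TEF. The peak-to-trough ratio was 4.58 for HLF, 3.29 for TEF, 3.17 for BHLHE41, 2.67 for NFIL3, 2.64 for NR1D2 and 2.25 for BHLHE40. CRY1 (ratio 2.98), DBP (2.21), RORA (1.52) and CLOCK (1.33) did not pass. Single arrays moved some of these: on the log2 scale CRY1 was 1.57 with all arrays, 0.68 without 11 PM and 2.55 without 3 AM, and DBP was 1.14 with all arrays and 1.81 without 3 PM, with CRY1 past the unadjusted threshold without 3 AM and DBP without 11 AM. PER3, CRY2 and BMAL2 lay below the level filter, with mean intensities of 48.0, 59.5 and 80.9, and PER1 and NR1D1 were represented only by probe sets that name several genes. The list's median F of 8.48 lay above that of all 10000 matched random lists, whose median was 0.842. Those lists were matched on expression alone, not on how members vary together over the same animals, so this does not test a rhythm. A second probe set of PER2, BMAL1, NPAS2 and BHLHE40 peaked at 8.04 h, 17.7 h, 21.6 h and 5.30 h, whereas second probe sets of HLF and RORA peaked at 11.7 h and 19.7 h. The sizes differed between probe sets: the log2 peak-to-trough difference was 1.14 on the second probe set of PER2 against 2.83, and 0.51 on that of HLF against 2.20. All 9 passing genes peaked within 3 h of the peak or trough of age. A straight line on age gave a higher R2 than the cosine for BHLHE41 (0.952 against 0.900) and BHLHE40 (0.944 against 0.929). For the others the cosine, which has 1 more term, gave the higher R2, as for NR1D2 (0.826 against 0.820) and PER2 (0.989 against 0.678). With age as a covariate 2 clock genes passed, PER2 and CRY1. That fit's peak-to-trough difference exceeded the observed range for 7 of the 13 genes, among them CRY1 (log2 6.63, observed range 2.56). PER2 stayed within it (log2 2.13, observed range 2.66). Without the 7 PM array 1 clock gene passed over the list alone, and without the 7 AM array 5 did; the ratio without the 7 PM array was 2.56 for HLF and 1.86 for TEF.

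**Figure D1:**
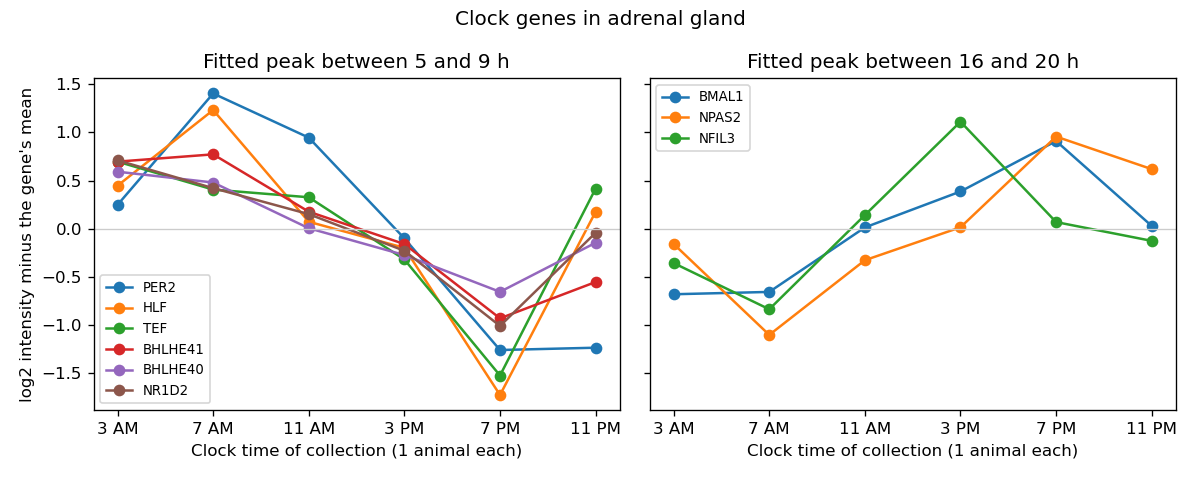
Log2 intensity of 9 clock genes minus each gene's mean, by clock time of collection, 1 animal per point and no error bars because no time was replicated. PER2 is highest at 7 AM and lowest at 7 PM, and BMAL1 is highest at 7 PM.

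Across all genes tested, after PER2, the smallest p values belonged to PLCB4, a phospholipase C (peak 5.21 times its trough, at 10.5 h), NMB, which encodes the peptide neuromedin B (4.60 times, 19.2 h), DIAPH1, an actin-nucleating formin (4.25 times, 0.799 h), and NDUFC1, a subunit of respiratory complex I (4.17 times, 14.6 h). HYOU1, an endoplasmic reticulum chaperone, reached 4.04 times its trough at 13.4 h, with intensities from 424 at 11 PM to 1696 at 11 AM. The serotonin receptor gene HTR4 (3.10 times) and malic enzyme ME1 (3.07 times) peaked at 19.4 h and 21.8 h, and the chemokine receptor gene CXCR4 (3.79 times) at 8.38 h. MRPS16, a mitochondrial ribosomal protein gene, peaked at 1.16 h and NMNAT2, which makes NAD, at 11.9 h. A second probe set of ME1 had a log2 peak-to-trough difference of 0.30, against 1.62 for the one tested, and the other probe sets of CXCR4 had 1.22 and 0.36, against 1.92. With age as a covariate the log2 difference of NMB was 1.03, against 2.20 without it, and no longer passed the unadjusted threshold.

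None of these passed adjustment over all genes. By limma's moderated F test 0 of 7164 genes had an adjusted p under 0.05, the lowest being 0.219 for PER2, and 398 genes had an unadjusted p under 0.05, against 358.2 expected by chance. The ordinary F test also gave 0, with 412 at the unadjusted threshold. All 398 had a fitted peak at least 1.5 times the trough, with a median of 2.21 and a range of 1.69 to 9.98. Their peaks were spread over the day, from 52 between 0 and 4 h to 84 between 16 and 20 h. The median standard error of a log2 peak-to-trough difference was 0.31.

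**Figure D2:**
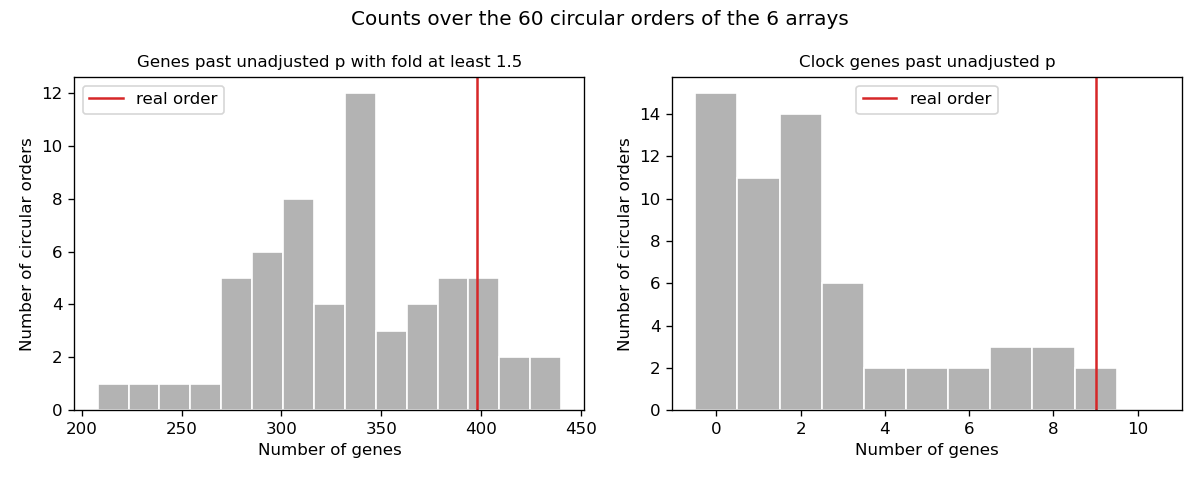
Number of genes past the unadjusted threshold (left) and of clock genes past it (right) in each of the 60 circular orders of the 6 arrays, with the real order as a line. The real order gives 398 genes and 9 clock genes.

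Genes of adrenal steroid production did not pass the list test. The 14 tested genes of steroidogenesis and the ACTH receptor had fitted peaks between 15.9 h, for FDX1, and 23.9 h, for MC2R, and all 14 lay above their own mean at 11 PM, as did 13 at 7 PM. Their smallest p values belonged to SULT2A1, which sulphates DHEA (peak 2.06 times its trough), and POR, the electron donor to the steroid hydroxylases (2.55 times). On the log2 scale POR was 1.35 with all arrays, 0.72 without 11 PM and 2.00 without 3 AM. Cholesterol synthesis and uptake, which supplies the precursor, peaked at 20.5 h in its mean, and all 15 members peaked within 6 h of that time, among them MVD (2.41 times) and the hormone-sensitive lipase LIPE (3.34 times, log2 1.74, with 1.05 without the 3 PM array and 2.55 without 11 AM). Such a window follows the members' own mean, and all 8 heat shock genes and 15 of 16 immediate early genes met theirs too. For cholesterol R2 was 0.915 (exact p = 0.0333), and for steroidogenesis 0.672 (exact p = 0.25). Adjusted over lists these were both 0.641, but with a smallest exact p of 0.0167 no list could pass this adjustment on its own. Under quantile normalization the exact p for steroidogenesis was 0.0333, with 0.4 when arrays were centred on the median, and for cholesterol the alternatives ran from 0.0333 to 0.0667. No member of either list passed over the list alone. Fitted age had its trough at 18.2 h, near the peaks of both list means (20.1 h for steroidogenesis). Correlation with age ran from -0.98 for CYP17A1 to -0.03 for MC2R among steroidogenesis genes. Among cholesterol genes it ran from -0.97 for MVD to 0.06 for LIPE. A cosine on age had an R2 of 0.947, so the order test does not separate age from clock time here.

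Chromaffin genes lay highest at 7 AM and lowest at 3 AM, in the list mean by 0.54 above and -0.59 from the gene means on the log2 scale (R2 0.627, exact p = 0.267). Immediate early genes, induced within minutes of stimulation, were lowest at 7 PM, where 0 of 16 exceeded their own mean. The exact p was 0.233 for the clock list mean, whose members run opposite to one another (0.0167, the smallest possible, for its first principal component), 0.7 for clock kinases, 0.483 for immediate early genes, 0.417 for glucocorticoid-responsive genes, 0.383 for heat shock genes, 0.85 for Wnt and zona glomerulosa genes, 0.183 for oxidative phosphorylation, 0.667 for the proteasome, 0.467 for ribosomal proteins and 0.333 for the cell cycle. Among marker lists it was 0.0833 for lymphocytes, 0.133 for endothelial cells, 0.217 for kidney, 0.367 for adipocytes, 0.417 for fibroblasts and capsule, 0.533 for macrophages and 0.817 for smooth muscle. These p values do not measure differences between single arrays. Smooth muscle markers lay at -1.24 from the gene means at 11 PM, with 0 of 5 above their own mean, and at 0.71 at 7 PM. Adipocyte markers lay at 0.65 at 3 AM and -0.72 at 3 PM. Red blood cell and glial markers had 2 and 1 tested members and were not tested as lists. Because the smallest exact p is 0.0167, no list could pass adjustment across lists on its own, and a count of 0 there is no evidence against a rhythm. After this adjustment 0 passed the exact order test, with 1, cholesterol, at an unadjusted p under 0.05. That number ran from 0 to 3 over the alternatives, and for endothelial cells the exact p was 0.0333 under quantile normalization, centring on the median and the first principal component, with 0.267 at most under the others. LPL, a lipase of adipocytes, passed over the list alone (adjusted p = 0.0390), but not without the 3 AM, 3 PM, 7 PM or 11 PM array.

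**Figure D3:**
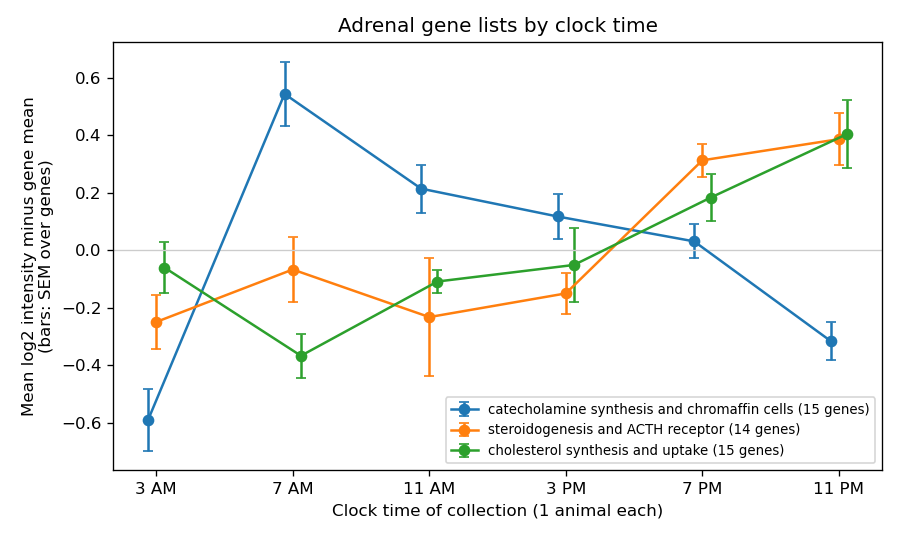
Mean log2 intensity minus gene mean for chromaffin genes (15), steroidogenesis genes (14) and cholesterol genes (15), by clock time, 1 animal per time. Bars are the SEM over genes, not over animals; the chromaffin mean is highest at 7 AM and lowest at 3 AM.

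Between the daytime arrays (7 AM to 3 PM) and the night arrays (7 PM to 3 AM), genes of the adrenal medulla all lay on one side. All 15 chromaffin genes were higher by day, by a mean of 0.58 on the log2 scale, with TH, the rate-limiting enzyme of catecholamine synthesis, at 1.09 ± 0.31 (SE), PNMT, which makes adrenaline from noradrenaline, at 1.10 ± 0.29, and the transcription factor GATA3 at 0.93 ± 0.26. These 3 passed when adjusted over the list alone and 0 passed over all genes tested; over the list alone 0 passed without the 3 AM, the 7 AM or the 11 PM array, 1 without 3 PM, and 5 without 11 AM or 7 PM. Steroidogenesis genes were lower by day by a mean log2 difference of -0.30, with 3 of 14 higher, and cholesterol genes by -0.35, with 1 of 15 higher. Adipocyte markers were lower by day in 3 of 3 genes, by a mean of -0.77, with LPL and FABP4 passing over the list alone, and 0 passing without the 3 AM, 7 AM, 3 PM or 11 PM array. Of the other lists, 1 immediate early gene, the nuclear receptor gene NR4A2 (1.11 ± 0.25), and 1 lymphocyte marker, the T-cell surface gene CD2 (0.84 ± 0.25), were higher by day and passed over the list alone. NR4A2 did not pass without the 3 AM, 7 AM, 11 AM or 7 PM array, nor CD2 without 3 AM, 7 AM, 3 PM or 11 PM, and without 11 PM 3 immediate early genes passed.

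With camera's preset correlation, chromaffin genes (adjusted p = 8.08e-08), immediate early genes (adjusted p = 0.0142), macrophage markers (adjusted p = 0.0166) and ribosomal proteins (adjusted p = 0.0232) were higher by day, and cholesterol (adjusted p = 0.0017), adipocyte (adjusted p = 0.00259), steroidogenesis (adjusted p = 0.0138) and oxidative phosphorylation genes (adjusted p = 0.0158) were lower. None of these calls held: for chromaffin, macrophage, cholesterol, adipocyte and oxidative phosphorylation genes the adjusted p = 0.349 with an estimated correlation, and for the other 3 lists the adjusted p = 0.609 with an estimated correlation.

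Single genes with the smallest p were creatine kinase CKB (2.37-fold higher by day), the tyrosine kinase gene BLK (2.43-fold) and PLCB4 (3.01-fold), and, in the other direction, the sulphide oxidoreductase SQOR (2.94-fold higher by night), the adaptor gene GRB14 (2.28-fold) and TNFSF10, the death ligand TRAIL (1.87-fold). By limma 0 of 7164 genes differed after adjustment (lowest adjusted p = 0.443), and 386 had an unadjusted p under 0.05, 211 higher and 175 lower by day. By chance 358.2 would be expected, and 4 of the 10 splits, the real one included, gave 386 or more.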

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

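The fits without the 3 AM and 3 PM arrays and the ordinary F test of the clock genes were chosen only after the results were seen. Counts of genes past adjustment over all genes were 0 in the cosine fit under every alternative except the stricter filter on level, where PER2 passed (1 gene, 3804 tested, adjusted p = 0.0326); fewer genes were tested there. In the daytime contrast 1 gene, TBCE, passed with the day split at 3 PM, which also parts the oldest animals from the youngest. Leaving out 1 array in turn gave 0 to 1, the 1 being IRGQ without 11 PM. The looser count of 398 became 621 with no filter, 244 with the stricter filter, 604 with every probe set on its own, all with other numbers of tests, and 265 with the ordinary F test; without single arrays it ran from 362 to 536. The 9 clock genes became 4 with no filter, 2 with age as a covariate and 1 with the ordinary F test, and 1 to 8 without single arrays, 1 without 7 PM and 5 without 7 AM. Without the 3 AM and 3 PM arrays 6 passed. So few arrays leave hardly any residual freedom, and that fit rests mostly on limma's prior (4.60 degrees of freedom). Lists past adjustment numbered 0 under every alternative run, where no list could pass on its own. With an array left out or age as a covariate the order test was not run. With age as a covariate the log2 peak-to-trough difference was 0.49 for BHLHE41 and 0.34 for MVD, with peaks moved by over 6 h; apart from the number of genes tested and of arrays left out, the cause was not tested for any of these changes. Apart from these 2 moved peaks, the alternatives for named genes kept the side of the unadjusted threshold in 879 cases. They lost it in 103 and gained it in 40, with age as a covariate and arrays left out included. The 879 include genes past the threshold in neither fit, so they do not measure how stable the calls were. No paired analysis was possible because each clock time has 1 animal. Signal over background was not given, so low-signal genes are limited by the level filter alone.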

Other observations

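The tests of the clock count over orders, of PER2 with age as a covariate, of the clock genes in animals of nearly equal age and both tests of the chromaffin list were chosen only after the result was seen. Beyond the groups above, glucocorticoid-responsive genes had a median F of 2.67, at percentile 99.9 of matched random lists. Among them NFKBIA peaked at 5.24 h (2.53 times its trough) and GLUL at 1.32 h (1.79 times). Steroidogenesis genes lay at percentile 99.1, lymphocyte markers at 97.6, chromaffin genes at 96.2 and adipocyte markers at 96.0. The random lists were not matched on how members vary together. The exact order test gave p = 0.417 for glucocorticoid-responsive and 0.25 for steroidogenesis genes. Of 17 other endoplasmic reticulum chaperone and stress genes, a list chosen after HYOU1 was seen, 0 had an unadjusted p under 0.05 by limma, the largest peak-to-trough ratio was 1.63 and the list mean gave an exact p of 0.383.

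The number of genes with a 24-h cosine can be set against the other circular orders. For the looser count, 6 of the 60 orders gave 398 or more, with a highest other of 440, so chance is not excluded. For genes past adjustment the real order gave 0 and the highest other 1, and a count of 0 tests nothing. Without the 3 AM and 3 PM arrays, whose hybridisation controls were weakest, the looser count was 433, in a fit that rests mostly on limma's prior. Age stays open: 58.3% of the 398 genes (exact binomial 95% interval 53.3 to 63.2) peaked within 3 h of the age axis, and 15 of the 60 orders gave as high a share. The interval treats genes measured in the same animals as independent and is therefore too narrow. The share of medulla in the piece of gland also stays open, with an R2 of 0.627 for the chromaffin mean.

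For the clock genes, 2 of the 60 orders gave 9 or more past the unadjusted threshold, the real one included, and the highest other gave 9. This test was chosen after the count was seen, so it does not exclude chance. In the other order with 9 genes, a cosine on age also had an R2 of 0.947. The planned order test of the list mean gave an exact p of 0.233, but the members run opposite to one another and partly cancel in that mean. For the list's first principal component the exact p was 0.0167, the smallest possible. Neither passed adjustment across lists, which no list could pass on its own, and neither separates age from clock time. The count of clock genes past the unadjusted threshold fell to 5 without the 7 PM array. Age or a circadian rhythm may account for the pattern, since 100% of the 9 genes peaked within 3 h of the age axis. PER2 differed by 1.16 on the log2 scale from 3 AM to 7 AM and by -1.14 from 3 PM to 11 PM, between animals of nearly equal age, which age alone would not give. With age as a covariate it kept a log2 peak-to-trough difference of 2.13 ± 0.82 (SE), within its observed range of 2.66 (limma adjusted p = 0.0149 over the list alone). The same fit exceeded the observed range for 7 of 13 clock genes, so it does not settle the question on its own. Between animals of nearly equal age the 9 genes differed by a median log2 of 0.51, at percentile 96.5 of lists matched on expression and 94.4 of genes that also passed on the age axis; without PER2 the latter was 43.4, and all 13 tested genes lay at 82.5 of matched lists. PER2 was not the only clock gene to differ between these animals. From 3 AM to 7 AM and from 3 PM to 11 PM, NPAS2 differed by -0.94 and 0.60 and NFIL3 by -0.48 and -1.24. BHLHE40 differed by only -0.11 and 0.13, and BHLHE41 by 0.08 and -0.39. With 1 animal per time, age, clock time and differences between animals cannot be told apart for the clock genes other than PER2 as a set. For PER2, clock time cannot be told from differences between single animals.

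For the chromaffin genes, compression of high signals on the 3 AM array is argued against by quantile normalization, which left a list mean of 0.57 against 0.58, while it took the ribosomal list from 0.16 to 0.05. A different share of medulla in the pieces of gland could give the pattern: the 15 differences ran from 0.07 for CYB561 to 1.10 for PNMT, with a spread 1.18 times their median standard error. That ratio was roughly known when the limits of its test were set, so it does not count as evidence for this explanation, which stays open beside a regulation of these genes. Without the 3 AM array the list mean was 0.43, and without the 7 AM array 0.46, with 15 of 15 genes higher by day in each. On the 3 AM array, lowest for chromaffin genes, steroidogenesis genes lay at -0.25 from the gene means, 2 of 14 above their own. Adipocyte and smooth muscle markers lay at 0.65 and 0.55 there, and macrophage and lymphocyte markers at -0.25 and -0.23. At 11 PM chromaffin genes lay at -0.32 and steroidogenesis genes at 0.39. Shares of tissues other than medulla were not tested as a cause. In the daytime contrast the real split gave 0 genes past adjustment and the highest other 1, in the split that parts the oldest animals from the youngest. In any case 10 splits are too few for a share under 0.05.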
